A study of Mus musculus with 18 samples.

How the data were processed

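The authors deposited, per the file headers, a table of RSEM output with expected counts and TPM for each gene, and a signal that the labels describe as median-normalized TPM. Per the labels the libraries were made from poly-A RNA, and the authors' processing used Bowtie 0.12.8 and RSEM 1.2.3 with the mm10 build of the mouse genome. Of the expected counts 21.5% were not whole numbers, and they were rounded to whole counts before testing. All columns of values were assigned to a sample, with 0 left over. Genes were matched by Ensembl identifier to GENCODE vM21 on GRCm38, which may not be the release the authors used, and 21856 of 21954 genes (99.55%) were found there. Positions are taken from that release. No genome sequence or reads were used here.

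The groups, the 9 comparisons, the alternatives and the naming rule were fixed before the data were examined. The comparisons were knockout against wild type in each treatment, each cytokine against untreated cells in each genotype, and the difference of each response between genotypes. Counts were filtered with filterByExpr, leaving 12514 genes, normalized by TMM, and tested with the robust quasi-likelihood fit of edgeR 4.0.16 in R 4.3.3 on all 18 libraries with 1 coefficient per group. The biological coefficient of variation was 0.301. P-values were adjusted by the method of Benjamini and Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Standard errors of genes are the size of the log2 fold change over the square root of F. Those of list medians come from resampling the genes of the list (bootstrap) and hold the libraries fixed. Other tests were DESeq2 1.42.0, limma 3.58.1 on log2 of the deposited TPM plus 1 or 0.1, and the exact permutation test for Rpl13a and Lyz2. Where a group held 0 counts the fold is given as a lower bound against 3 counts over the group, and where it held 1 to 3 counts as a ratio with an exact 95% counting interval.

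The naming rule took, per comparison, called genes with a mean of at least 5 CPM in the higher group and no overlap of the groups, up to 8 largest rises and 8 largest falls, or 6 and 6 for a difference of responses. It added up to 4 members with the lowest p of each list that was called or had at least 3 called members. It also added 17 preset genes, which were Rpl13a, Lyz2 and markers of interferon, IL4, the GAIT complex and macrophages. Where no gene was called, the 4 with the lowest p were given as values. Predicted genes and pseudogenes were counted but not named, with the exception of Gm2000, and the text gives a selection of the named genes. Some results are not reported here. Genes named outside the rule are marked as chosen after their values were seen.

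The 33 gene lists were fixed from textbook knowledge, and 29 had at least 5 tested members. Camera was run on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. As this correlation can be too small for genes that vary together between libraries, camera with a correlation estimated per list and fry were run beside it. Counts of members adjusted over the list alone apply the same adjustment to the p-values of that list.

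The methods were tested on simulated data of 12514 genes. For untreated knockout against wild type 1.493% of genes simulated at 1.5-fold, 46.27% at 2-fold and 84.85% at 4-fold were recovered, with 7 false calls. For the IFN response of wild type the shares were 11.94%, 46.27% and 75.76% with 8 false calls, and for the difference of the IFN responses 8.955%, 13.43% and 74.24% with 1. Small changes in the comparisons of genotypes were thus mostly out of reach. The simulated counts were drawn independently for each gene and library, without the shared deviations between libraries that the real data hold. The false calls therefore do not measure errors that such structure can cause.

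The number in the title was examined as a possible pairing of knockout and wild type libraries, through the correlation of their deviations from the group means across genes, which are not independent replicates. In IL4-treated cells the same numbers correlated at 0.702, 0.561 and 0.475 over 9712 genes with a mean log2 CPM above 2, and at 0.586, 0.323 and 0.449 over all 12514, each the best match of its library. The IL4 comparison was therefore also given with the number as a block. Wild type untreated libraries 2 and 3 were much closer to each other than other replicates, with a chi-square per degree of freedom of 6 where the other pairs ran from 51.5 to 184, and were kept as separate libraries. No library was left out.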

Results

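RNA was sequenced from bone marrow derived macrophages of mice, grown from wild type animals (called control in the labels) or from animals in which the gene for ribosomal protein L13a was knocked out in macrophages. L13a is a protein of the large ribosomal subunit. When interferon-gamma acts on myeloid cells, it is released from the ribosome and takes part in the GAIT complex, which silences the translation of a group of inflammatory transcripts. Cells of each genotype were left untreated, treated with IFN, or treated with interleukin-4 (IL4), named in the labels as cytokines of the M1 and M2 states. The labels do not name the type of interferon. The 6 groups held 3 libraries each, 18 in all, and total expected counts per library ran from 18098711 to 28477342 over 21954 genes. Of these genes 12514 passed the filter on low counts. Libraries are named here by the number in their titles: 1, 2 and 3 were untreated, 4, 5 and 6 received IFN, and 7, 8 and 9 received IL4, in both genotypes. No label says whether the 3 libraries of a group came from separate animals or cultures, so how far the p-values measure spread between animals is not known. Transcripts of the Y-linked genes Ddx3y, Eif2s3y and Uty were present in 5 of the 9 wild type libraries (untreated 1, IFN 4 and 5, IL4 7 and 8), with a summed level of at least 116 CPM. None of the 9 knockout libraries held them above 0.143 CPM. Each wild type group thus held libraries with and without them, so its 3 libraries did not all come from a single donor. Levels are TMM-normalized CPM, given as mean ± SD over n = 3 libraries, and changes are log2 fold changes with a standard error (SE) and the adjusted p of edgeR's quasi-likelihood test unless another test is named. Genes named as called had an adjusted p under 0.05. Positions are 1-based on GRCm38, and ratios with intervals and lower bounds of folds cover counting error only.

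The targeted gene was Rpl13a (ENSMUSG00000074129, chromosome 7, 45125558 to 45128761, minus strand). Its transcripts were lower in the knockout libraries on average but were present in all of them. In untreated cells Rpl13a stood at 253 ± 130 CPM in the knockout against 703 ± 73.8 CPM in wild type (SD, n = 3 each), or 36% of the wild type mean. The separate knockout libraries 1, 2 and 3 held 156.2, 201.4 and 400.5 CPM. After IFN the means were 287 ± 123 and 536 ± 91.3 CPM, or 53.6%, with 247.8, 188.9 and 424.8 CPM in knockout libraries 4, 5 and 6. After IL4 they were 382 ± 204 and 736 ± 135 CPM, or 51.9%, with 206.3, 332.6 and 605.9 CPM in knockout libraries 7, 8 and 9. The groups did not overlap in untreated or IFN-treated cells (10% of genes would part 3 against 3 by chance), while knockout IL4 library 9 exceeded the lowest wild type IL4 library at 597.6 CPM. The two-sided exact permutation p was 0.1, 0.1 and 0.2, and 0.1 is the smallest that 3 against 3 can give. In each treatment the knockout library with the most Rpl13a (3, 6 and 9) also held the most fibroblast marker transcripts, at 502.2, 814.6 and 1215 CPM against at most 236.1 CPM in the other knockout libraries. It also held the most Mki67, a marker of dividing cells, at 187.9, 76.83 and 237.6 CPM. The order was not particular to the knockout. Wild type libraries 3, 6 and 9 likewise held the most Rpl13a of their groups (745.9, 617.6 and 866.5 CPM) and the most fibroblast marker transcripts (1024, 171.7 and 538.7 CPM). Among the other knockout libraries, 2 held more Rpl13a than 1, and 4 more than 5, but both held less of the fibroblast markers. Knockout library 8 held more of both than 7. The log2 fold changes were -1.47 (SE 0.392, adjusted p = 0.256), -0.90 (SE 0.388, adjusted p = 0.772) and -0.95 (SE 0.388, adjusted p = 1), so Rpl13a was not called in any treatment. DESeq2 called it in untreated cells (adjusted p = 0.0303). The files count whole genes, so they do not show which exons the transcripts held, and processed copies of Rpl13a elsewhere in the genome could share its reads. The labels of genotype rest on Rpl13a as a group mean and on Lyz2, whose level parted the genotypes without overlap.

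**Figure D1:**
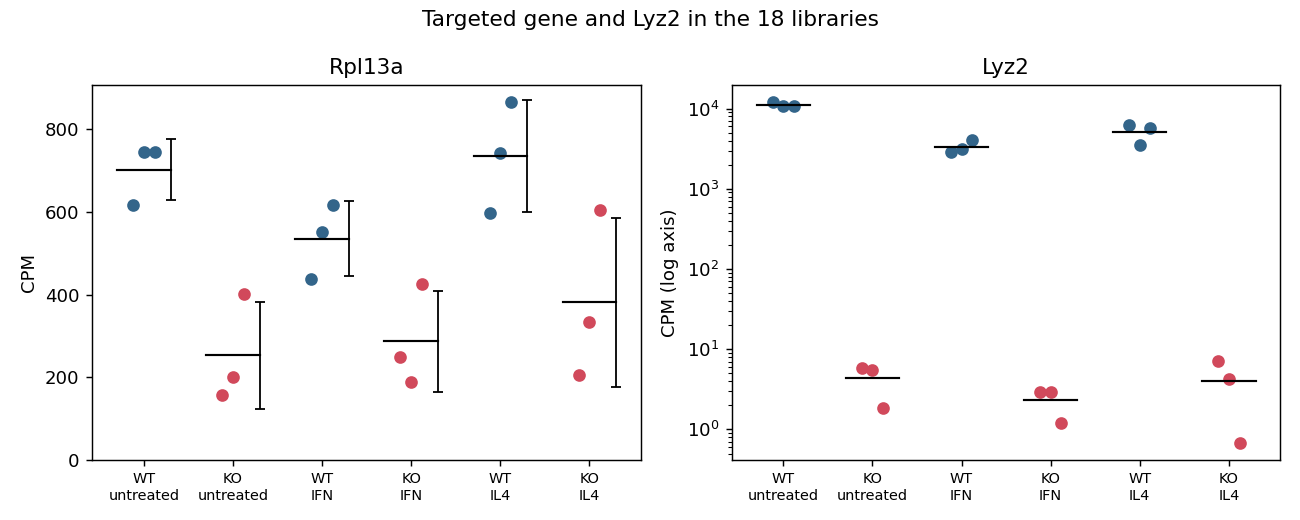
Rpl13a in CPM on a linear axis with the mean and SD of each group, and Lyz2 in CPM on a log axis with the group mean, one point per library. Knockout libraries held 156.2 to 605.9 CPM of Rpl13a, and at most 7.122 CPM of Lyz2 where wild type held at least 2881 CPM.

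The first comparison asked what differed between knockout and wild type in untreated macrophages. Lyz2 was nearly lost in every knockout library. No comparison of genotypes can therefore tell loss of L13a apart from loss of Lyz2 or a change at its locus. Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321, minus strand), which encodes the lysozyme of macrophages and whose locus carries the Cre recombinase in a widely used macrophage deleter strain, stood at 4.37 ± 2.19 CPM in the knockout. In wild type it stood at 11200 ± 801 CPM. Its log2 fold change was -11.34 (SE 0.625, adjusted p = 8.65e-08). Cnbd2 (chromosome 2, 156312299 to 156375638) fell from 46.8 ± 8.94 to 8.51 ± 3.65 CPM (log2 -2.45, SE 0.329, adjusted p = 0.00861). Dynlt1b, a light chain of the dynein motor, fell from 97.5 ± 14.8 to 42.6 ± 5.81 CPM (log2 -1.20, adjusted p = 0.0109), and the ribosomal protein transcript Rpl26 from 639 ± 78.7 to 325 ± 57.4 CPM (log2 -0.97, adjusted p = 0.0341). Ibsp, a protein of bone matrix, was at 0.0612 ± 0.0691 CPM against 19.4 ± 15.9 CPM (log2 -8.15, SE 1.31, adjusted p = 0.0152). Wild type untreated 1 stood apart with Ibsp at 1.22 CPM, against 31 and 25.9 CPM in wild type untreated 2 and 3. On the higher side were Pira2 (chromosome 7, 3836812 to 3845051), an activating receptor of myeloid cells, at 157 ± 44 against 39.4 ± 9.09 CPM (log2 2.00, SE 0.322, adjusted p = 0.0224), and Fam177a (chromosome 12, 55124469 to 55142104), at 59 ± 8.44 against 28.7 ± 3.18 CPM (log2 1.04, SE 0.146, adjusted p = 0.00861). Pira2 and the lysozyme genes have near copies in the genome, so their counts are uncertain to that extent.

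edgeR called 10 genes in untreated cells, 2 higher and 8 lower in the knockout, among 944 with an unadjusted p under 0.05. The remaining 3 calls, chosen for naming after their values were seen, were Alpl (log2 -3.86, adjusted p = 0.00861), Rbm44 (log2 -3.79, adjusted p = 0.0109) and Clec11a (log2 -3.07, adjusted p = 0.0429). Alpl, like Ibsp, is a transcript of bone-forming cells. DESeq2 called 83 genes, a fit on the 6 untreated libraries alone called 1, and the presence of Y-linked transcripts as a covariate gave 39. The count fell to 1 without wild type untreated 2, to 6 without wild type untreated 3, to 3 without knockout untreated 1 and to 2 without knockout untreated 2. Lyz2 kept its call in each of these fits.

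Of 29 fixed gene lists, camera called 10 in untreated cells, and 0 with an estimated correlation. Cytosolic ribosomal protein transcripts, Rpl13a left out, stood lower in the knockout. Of 80 tested, 79 had a log2 fold change below 0, 1 was called and 62 were lower when adjusted over the list alone, with a median of -0.74 (camera adjusted p = 4.71e-58; adjusted p = 0.499 with an estimated correlation). Rpl17 was at 360 ± 69.3 against 783 ± 111 CPM (log2 -1.12, adjusted p = 0.0566), Rps27 at 108 ± 16.3 against 299 ± 73.8 CPM (adjusted p = 0.066) and Rps14 at 349 ± 87 against 810 ± 110 CPM (adjusted p = 0.073). Oxidative phosphorylation transcripts had a median of -0.28 over 75 genes (camera adjusted p = 2.04e-10), and Cox7c was at 49.6 ± 2.63 against 83.2 ± 10.2 CPM. Type I interferon response genes had a median of -0.66 over 44 genes (camera adjusted p = 5.24e-08), interferon-gamma response genes -0.14 over 38 (0.0365) and cell cycle genes -0.45 over 45 (4.81e-07). Among these, Zbp1 was at 2.62 ± 1.06 against 8.28 ± 3.1 CPM, Oasl2 at 42.5 ± 8.87 against 101 ± 43.4 CPM, Fcgr1 at 56.5 ± 14.6 against 107 ± 10 CPM and Birc5 at 40.4 ± 31.4 against 84.2 ± 27.5 CPM. Wild type untreated 1 stood nearer the knockout in Oasl2, at 51.3 CPM against 124 and 129 CPM in wild type untreated 2 and 3, 2 libraries that were unusually alike. The cell cycle median rested on knockout untreated 1 and was -0.0874 without it (0.533), while Mcm7 was at 37.2, 67.2 and 132 CPM in knockout untreated 1, 2 and 3 and at 83.6 to 106 CPM in wild type. Among these knockout libraries, untreated 1 held the least Rpl13a (156.2 CPM) and untreated 3 the most (400.5 CPM). Without untreated 3 the median was -1.01. The interferon-gamma list lost its call without wild type untreated 2, knockout untreated 1 or knockout untreated 3. For these 4 lists adjusted p = 0.8 with an estimated correlation, as for all the lists that follow in this paragraph. Genes activated by p53, the transcription factor that responds to ribosomal and DNA damage, had a median of 0.32 over 25 genes (camera adjusted p = 0.000483), or 0.112 without knockout untreated 1 (0.0513). Of them 4 were higher when adjusted over the list alone and 0 over all genes, and the 4 with the lowest p were Aen, Cdkn1a (402 ± 71.9 against 218 ± 40.6 CPM, log2 0.88, adjusted p = 0.232), Phlda3 (41.9 ± 20.2 against 18.6 ± 4.42 CPM) and Zmat3. Glycolysis genes had a median of 0.19 over 20 genes (0.00365; Pfkl 75 ± 12.4 against 52.1 ± 1.46 CPM), glutathione and NRF2 targets 0.23 over 25 (0.00821; Hmox1 522 ± 124 against 290 ± 17.1 CPM) and dendritic cell markers 0.82 over 9 (0.0264; Cd24a 15.3 ± 2.14 against 8.7 ± 1.83 CPM), and each of these 3 lists lost its call when some single library was left out. Fibroblast markers had a median of -1.34 over 14 genes (8.99e-05), with Col1a1 at 58.5 ± 36.3 against 273 ± 76.6 CPM and Col1a2 at 42.4 ± 31.5 against 198 ± 10.5 CPM. Their summed level was 955.1 CPM in untreated wild type and 282 CPM in untreated knockout libraries, and the wild type group also held a library with Y-linked transcripts.

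Lists tied to the question of the study were not called in untreated cells. Members and kinases of the GAIT complex had a median of 0.0515 over 7 genes (camera adjusted p = 0.821), and the reporter transcripts studied as GAIT targets -0.55 over 5, or -0.39 with genes near 0 counts at their bounds (0.872). The genes beside Rpl13a on chromosome 7 had a median of -0.11 over 14 (0.658), and macrophage identity genes -0.0809 over 24 with Lyz2 the single call (0.183). Adgre1, which encodes F4/80, was at 2090 ± 427 against 1900 ± 168 CPM and Csf1r at 3730 ± 584 against 3470 ± 224 CPM. Vegfa (60 ± 45.8 against 35.1 ± 27.7 CPM), Ccl22 (3.3 ± 1.12 against 3.15 ± 1.86 CPM) and Cp (1.14 ± 0.651 against 1.61 ± 0.948 CPM) were not called. Nor were Irf1 (36.6 ± 7.67 against 36.4 ± 7.28 CPM), Nos2, Cxcl9, Cxcl10, Arg1, Chil3 and Mrc1, and Retnla had no count in either group. Cxcl13 did not pass the filter on low counts.

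The second comparison asked the same of IFN-treated cells. Lyz2 stood at 2.35 ± 1 CPM in the knockout and 3360 ± 647 CPM in wild type (log2 -10.46, SE 0.626, adjusted p = 2.94e-07). Cnbd2 fell from 65.7 ± 18.1 to 16 ± 5.35 CPM (log2 -2.04, adjusted p = 0.028). Rab4a, a GTPase of recycling endosomes (chromosome 8, 123805985 to 123835287), fell from 8.26 ± 0.0134 to 1.46 ± 0.266 CPM (log2 -2.51, SE 0.307, adjusted p = 0.00319). Camk2b, a calcium-dependent kinase, fell from 8.02 ± 0.754 to 2.01 ± 0.116 CPM (log2 -2.00, adjusted p = 0.0367). Lyz1, the lysozyme gene beside Lyz2 (chromosome 10, 117287797 to 117292868), rose from 0.736 ± 0.134 to 6.04 ± 2.39 CPM (log2 3.03, SE 0.501, adjusted p = 0.0344). Pira2 rose from 30.8 ± 11.1 to 156 ± 52.2 CPM (log2 2.34, adjusted p = 0.0126) and Fam177a from 27.6 ± 2.6 to 54.7 ± 8.54 CPM (log2 0.99, adjusted p = 0.0197). With Rbm44 (log2 -4.02, adjusted p = 0.0337, chosen after its values were seen) edgeR called 8 genes, 3 higher and 5 lower, among 724 with an unadjusted p under 0.05. DESeq2 called 42, the 6 IFN libraries alone gave 1, and the Y-linked covariate gave 5, of which 3 were among the 8. The count fell to 2 without wild type IFN 5 or knockout IFN 5, and to 3 without wild type IFN 4, wild type IFN 6 or knockout IFN 4.

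The preset interferon genes were not called between genotypes after IFN. Irf1 was at 856 ± 94.6 against 750 ± 70.8 CPM, Cxcl9 at 1450 ± 593 against 1130 ± 1090 CPM, Cxcl10 at 1120 ± 520 against 911 ± 715 CPM and Nos2 at 43.7 ± 47.4 against 32.7 ± 26.3 CPM, each with adjusted p = 1. Mrc1 was at 17.2 ± 8.41 against 41.1 ± 13.4 CPM (log2 -1.26, SE 0.381, adjusted p = 0.572), Vegfa at 146 ± 63.2 against 84.7 ± 30.7 CPM, Ccl22 at 2.97 ± 0.781 against 3.17 ± 1.39 CPM and Cp at 7.92 ± 8.63 against 5.03 ± 2.19 CPM. Adgre1 (2130 ± 698 against 1710 ± 481 CPM), Csf1r (3550 ± 130 against 3220 ± 177 CPM), Arg1 and Chil3 were not called, and Retnla had no count.

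Camera called 7 lists after IFN, and for each adjusted p = 0.773 with an estimated correlation. Cell cycle genes had a median of -0.94 (2.29e-24), with Mcm7 at 49.1 ± 25.9 against 111 ± 10.6 CPM, Mcm3 at 58.5 ± 28.6 against 122 ± 11.7 CPM and E2f1 at 41.7 ± 5.19 against 60.1 ± 8.81 CPM. Knockout IFN 6 stood apart, with Mcm7 at 79 CPM against 35.6 and 32.7 CPM in knockout IFN 4 and 5, and the cell cycle median was -1.60 without it. The p53 targets had a median of 0.39 (2.22e-07), or 0.213 without knockout IFN 4 (0.00745), and 5 were higher when adjusted over the list alone. Phlda3 was at 71.7 ± 31.7 against 21.7 ± 5.43 CPM (log2 1.72, SE 0.339, adjusted p = 0.149) and Cdkn1a at 918 ± 212 against 486 ± 30.2 CPM (log2 0.92, adjusted p = 0.372). Ribosome biogenesis genes had a median of -0.15 over 41 genes (0.00193; Bop1 38 ± 1.09 against 49.3 ± 1.8 CPM) and lysosome genes 0.17 over 36 (0.00168; Ctsh 1280 ± 235 against 908 ± 222 CPM). Both lists lost their calls without wild type IFN 5 (camera adjusted p = 0.0876 for each) or knockout IFN 5 (0.203 for each). Without knockout IFN 5 their medians were -0.072 and 0.101. Interferon-gamma response genes (median 0.20, 0.00444), MHC class I genes (0.23 over 23, 0.000222; B2m 8690 ± 1080 against 6390 ± 2150 CPM) and oxidative phosphorylation genes (0.14, 0.00105) were called upward, but with the Y-linked covariate the medians of these 3 lists were -0.0767, 0.0206 and -0.116. The only wild type IFN library without these transcripts was IFN 6, so that fit leaned on it. Single libraries moved the 3 medians too. The oxidative phosphorylation median turned to -0.0584 without wild type IFN 4, the MHC class I median was 0.0795 without it (0.0644) and 0.519 without wild type IFN 6, and the interferon-gamma median was 0.0728 without knockout IFN 5 (0.203), with its call also lost without wild type IFN 4 or 5. Ribosomal protein transcripts had a median of -0.00428 and a mean of 0.0491 (camera upward, adjusted p = 0.474), with 39 of 80 above 0. Fibroblast markers had a median of 1.16 (0.142), and their summed level ran from 42.57 to 814.6 CPM between the 3 knockout IFN libraries.

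In IL4-treated cells the same question gave Lyz2 at 4 ± 3.22 against 5170 ± 1430 CPM (log2 -10.30, SE 0.607, adjusted p = 2.34e-07). Cnbd2 fell from 50.7 ± 14.3 to 10.6 ± 2.52 CPM (log2 -2.27, adjusted p = 0.025) and Rab4a from 9.47 ± 1.93 to 2.81 ± 0.494 CPM (log2 -1.76, adjusted p = 0.025). Pira2 rose from 18.9 ± 7.83 to 76.8 ± 8.3 CPM (log2 2.03, adjusted p = 0.0309). Fam177a rose from 27.1 ± 1.84 to 51.1 ± 5.51 CPM (log2 0.91, adjusted p = 0.0285). Nnt, the mitochondrial transhydrogenase that some laboratory strains lack in part (chromosome 13, 119335448 to 119408997), rose from 26.2 ± 5.78 to 48.7 ± 2.55 CPM (log2 0.89, SE 0.142, adjusted p = 0.0285). Xlr4a on the X chromosome (log2 -3.29, adjusted p = 0.0436, chosen after its values were seen) was called as well. In all edgeR called 8 genes, 3 higher and 5 lower, among 308 with an unadjusted p under 0.05. With the number in the title as a block the count was 27, of which 14 were higher and 13 lower, and all 8 were among them. DESeq2 called 30, the 6 IL4 libraries alone gave 1, and the Y-linked covariate gave 3. Leaving out 1 library gave 4 without wild type IL4 7, 2 without wild type IL4 8 or 9, and 1 without knockout IL4 7, 8 or 9.

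The markers of IL4 activation did not part the genotypes in IL4-treated cells. Arg1, the arginase of alternatively activated macrophages, was at 692 ± 453 against 1000 ± 531 CPM, Retnla at 1130 ± 754 against 828 ± 901 CPM, Chil3 at 224 ± 147 against 151 ± 95.2 CPM, Mrc1 at 1740 ± 456 against 1770 ± 155 CPM and Ccl22 at 26.1 ± 15.4 against 23.8 ± 13.1 CPM, each with adjusted p = 1. Irf1, Nos2, Cxcl9, Cxcl10, Cp, Vegfa, Adgre1 and Csf1r had the same adjusted p. Of the 7 lists called by camera, ribosomal proteins had a median of -0.32 with 4 of 80 above 0 (1.59e-26; adjusted p = 0.618 with an estimated correlation) and Rps27 at 158 ± 7.67 against 302 ± 28.4 CPM. Their median was -0.171 without knockout IL4 7 (camera adjusted p = 5.09e-06). The p53 targets had a median of 0.35 (2.27e-10; adjusted p = 0.48 with an estimated correlation), 1 of them higher when adjusted over the list alone, and Phlda3 was at 97.2 ± 17.7 against 38.3 ± 6.34 CPM (log2 1.35, SE 0.327, adjusted p = 0.538). The p53 median was 0.181 without knockout IL4 7 (camera adjusted p = 0.0068). Inflammatory M1 genes had a median of 0.30 over 23 genes (0.000902; also adjusted p = 0.48 with an estimated correlation), with Cd80 at 12.1 ± 1.39 against 7.21 ± 2.33 CPM. This list lost its call without knockout IL4 7, with a median of 0.164 (camera adjusted p = 0.142). Cell cycle genes had a median of -0.37 (1.97e-10) and glutathione and NRF2 targets 0.25 (0.00463), both with adjusted p = 0.795 with an estimated correlation. The glutathione and NRF2 list lost its call without wild type IL4 7 (median 0.175, camera adjusted p = 0.195) or wild type IL4 9 (0.175, 0.0866). It also lost it without knockout IL4 8 (0.059, 0.776). The cell cycle median rested on knockout IL4 7 and was 0.0253 without it (0.919), while Mcm7 was at 36.5, 73 and 123 CPM in knockout IL4 7, 8 and 9 and at 91.2 to 107 CPM in wild type. Among these knockout libraries, IL4 7 held the least Rpl13a (206.3 CPM) and IL4 9 the most (605.9 CPM). Without IL4 9 the cell cycle median was -0.81. The type I interferon (-0.29, 0.0139) and oxidative phosphorylation medians (-0.12, 0.000902) had adjusted p = 0.882 with an estimated correlation, and single libraries turned both: 0.111 without wild type IL4 9 for the first, and 0.0718 without knockout IL4 7 for the second. With the Y-linked covariate both were larger, at -0.911 (1.26e-17) and -0.361 (2.48e-19). The only wild type IL4 library without these transcripts was IL4 9, so that fit leaned on it. Without IL4 9 in the main fit the oxidative phosphorylation median was -0.00426 (camera adjusted p = 0.339).

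**Figure D2:**
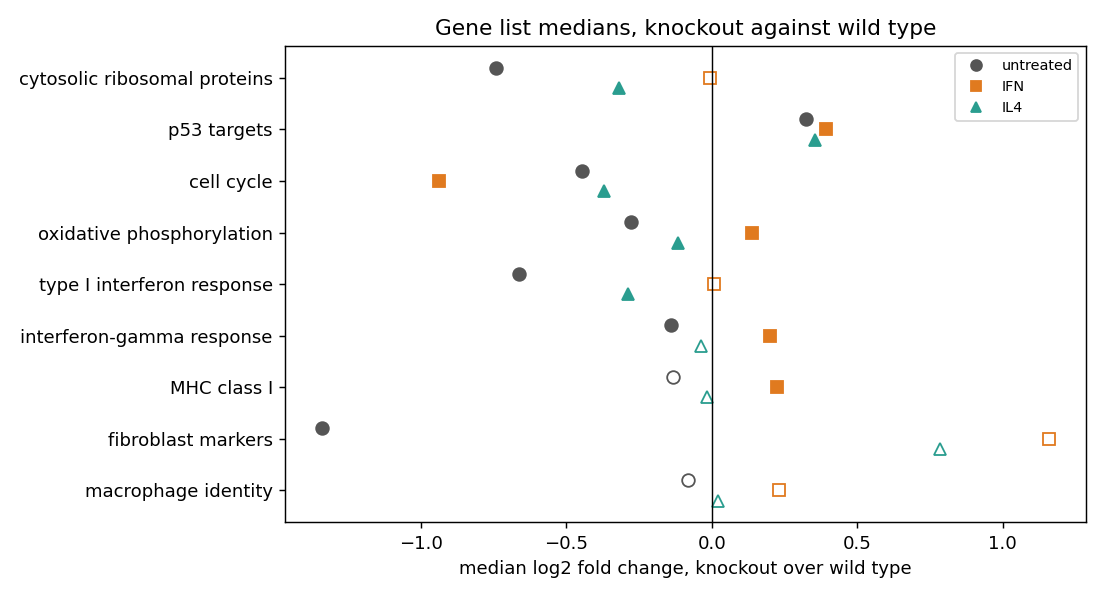
Median log2 fold change of knockout over wild type for 9 gene lists in untreated, IFN-treated and IL4-treated cells, filled where camera's adjusted p lay under 0.05 with its preset correlation and open otherwise. Ribosomal protein medians were -0.74, -0.00428 and -0.32, and those of the p53 targets 0.32, 0.39 and 0.35.

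Between treatments the knockout effects shared 6 genes called in the same direction in at least 2 treatments: Pira2 and Fam177a higher, and Lyz2, Cnbd2, Rab4a and Rbm44 lower. No gene was called in opposite directions. The lower calls of untreated and IFN-treated cells shared 3 genes where independent lists would share 0.0032 (Fisher's exact p = 1.71e-09). Across all tested genes, which are not independent replicates, the knockout log2 fold changes correlated at Pearson's r = 0.198 (Spearman's rho 0.121) between untreated and IFN-treated cells. The values were 0.328 (0.272) between untreated and IL4-treated and 0.468 (0.399) between IFN-treated and IL4-treated cells. These 3 comparisons shared no library. Libraries at the same position within their groups, such as knockout 3, 6 and 9, still deviated alike in part from the group means (r = 0.597 to 0.672). The overlaps and correlations can therefore hold agreement that is not due to genotype.

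The IFN response of wild type cells was measured as IFN against untreated libraries. Irf1, a transcription factor induced by interferons, rose from 36.4 ± 7.28 to 750 ± 70.8 CPM (log2 4.36, SE 0.376, adjusted p = 6.4e-07). The chemokines Cxcl9 and Cxcl10, which draw T cells, rose from 0.171 ± 0.238 to 1130 ± 1090 CPM (log2 12.85, adjusted p = 1.9e-08) and from 8.95 ± 5.5 to 911 ± 715 CPM (log2 6.69, adjusted p = 4.53e-05). Among the largest rises were the interferon-induced GTPases Gbp2b, from 0 counts to 192 ± 145 CPM (at least 4990-fold higher, taking 3 counts over the untreated group), Gbp10 (at least 2140-fold), and Tgtp1, from 0.226 ± 0.189 to 807 ± 340 CPM. Serpina3f, a serine protease inhibitor, was 11000-fold higher (95% counting interval 3780 to 53600), the receptor Clec9a 6080-fold (1090 to 240000) and the nuclease Dnase1l3 4750-fold (853 to 188000), and Tlr11, a sensor of parasite profilin, at least 345-fold. Nos2, the inducible nitric oxide synthase, rose to 32.7 ± 26.3 CPM, 2530-fold higher (453 to 99900; adjusted p = 2.08e-05). Cx3cr1, the fractalkine receptor, fell from 171 ± 30.6 to 6.74 ± 2.86 CPM (log2 -4.66, adjusted p = 8.32e-06). Adgre4 fell from 7.92 ± 3.36 to 0.0932 ± 0.0905 CPM (log2 -6.39) and the mannose receptor Mrc1 from 296 ± 12.3 to 41.1 ± 13.4 CPM (log2 -2.85, adjusted p = 5.91e-05). Ibsp reached 0 counts (at least 338-fold lower), and Slc6a4, Mamdc2, Slco2b1, Sult1a1 and Tmem26 completed the largest falls. Lyz2 fell from 11200 ± 801 to 3360 ± 647 CPM (log2 -1.74, adjusted p = 0.00646). Cp, Vegfa, Ccl22, Arg1, Chil3, Retnla, Csf1r, Adgre1 and Rpl13a were not called.

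edgeR called 2332 genes in wild type cells, 1387 higher and 945 lower after IFN, of which 758 and 562 changed at least 2-fold. Without the 5 libraries that held Y-linked transcripts, which left 1 wild type IFN library, it called 975, of which 918 were among the 2332. On log2(TPM + 1) 49.9% of limma's 2097 calls were higher against 59.5%. All 38 interferon-gamma response genes were called higher, with a median of 6.01 or 5.90 with bounds (camera adjusted p = 9.79e-55; adjusted p = 0.00149 with an estimated correlation), among them Gbp4 (0.75 ± 0.105 to 792 ± 124 CPM) and Iigp1 (1.49 ± 1.08 to 1690 ± 193 CPM). All 23 MHC class I genes were higher as well (median 2.39, 5.6e-24; 0.0269 with an estimated correlation), with Tap1 rising from 60.5 ± 8.16 to 717 ± 156 CPM. Of the 23 inflammatory M1 genes 13 were higher and 2 lower (median 2.22, 3.43e-07; 0.0269 with an estimated correlation), or 16 and 2 adjusted over the list alone, with Cd86 rising from 6.71 ± 1.29 to 141 ± 29.4 CPM. Camera called 13 lists, and the remaining 10 lost their calls with an estimated correlation. Type I interferon response genes were higher in 36 of 44, or 40 adjusted over the list alone (median 2.68, 2.53e-22; adjusted p = 0.143 with an estimated correlation), as was Mx1 (2.28 ± 0.333 to 122 ± 50 CPM). MHC class II genes were higher in 10 of 12, or 11 over the list alone (median 3.54, 8.63e-12; 0.0785 with an estimated correlation), as was Ciita (5.31 ± 1.19 to 202 ± 42 CPM). Integrated stress genes were higher in 14 of 26, or 15 (median 0.68, 2.39e-05; 0.0859 with an estimated correlation), as was Wars (51.1 ± 5.16 to 371 ± 45.8 CPM). Complement genes were higher in 8 of 18, or 10 with 1 lower (median 1.39, 0.000136; 0.184 with an estimated correlation), with C4b at 58.2 ± 34.9 against 0.117 ± 0.111 CPM. Glycolysis genes were higher in 8 of 20, or 11 with 1 lower (median 0.61, 3.24e-06; 0.0877 with an estimated correlation), with Hk3 at 1860 ± 151 against 203 ± 56.7 CPM. Oxidative phosphorylation genes were higher in 6 of 75, or 5 over the list alone (median 0.19, 0.0244; 0.925 with an estimated correlation).

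On the lower side in wild type, 9 of 25 glutathione and NRF2 targets fell over all genes and also over the list alone (median -0.53, 6.55e-05; adjusted p = 0.307 with an estimated correlation), such as Cat (399 ± 9.79 to 168 ± 46.8 CPM) and Gstm1 (152 ± 19 to 46 ± 6.83 CPM). Osteoclast markers included 5 lower and 1 higher of 8, or 6 and 1 over the list alone (median -2.02, 0.0155; 0.127 with an estimated correlation), with Atp6v0d2 at 30.8 ± 11.3 against 126 ± 35.2 CPM and Ocstamp at 97.3 ± 37.5 against 6.38 ± 2.88 CPM. Ribosomal proteins had a median of -0.35 (1.84e-06; 0.788 with an estimated correlation), with Rps21 the single call (181 ± 83.3 against 319 ± 65.6 CPM, adjusted p = 0.0493) and 0 adjusted over the list alone. Fibroblast markers fell in 8 of 14, or 11 over the list alone (median -2.67, 0.000157; 0.53 with an estimated correlation), with Col1a1 at 33.8 ± 9.77 against 273 ± 76.6 CPM. Of 37 IL4 M2 genes 6 were higher and 5 lower (median -0.18, 0.878), of 24 chemokines 7 and 3 (median -0.22, mean 0.457, 0.589), of 11 chemokine receptors 3 and 2, of 36 lysosome genes 8 and 2 and of 24 macrophage identity genes 3 and 4. Tgm2 rose from 225 ± 82.3 to 1850 ± 257 CPM, Ctsc from 282 ± 44.7 to 3030 ± 235 CPM and Fcgr1 from 107 ± 10 to 960 ± 342 CPM, while Cxcr4 fell from 140 ± 60.4 to 15.6 ± 5.76 CPM.

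The knockout cells' IFN response was large in the same genes. Irf1 rose from 36.6 ± 7.67 to 856 ± 94.6 CPM (log2 4.55, SE 0.379, adjusted p = 3.8e-07), Cxcl9 from 0.0794 ± 0.138 to 1450 ± 593 CPM (log2 14.39, adjusted p = 1.11e-08) and Cxcl10 from 7.49 ± 6.53 to 1120 ± 520 CPM (log2 7.22). Serpina3f rose from 0 counts to 411 ± 33.8 CPM (at least 11100-fold), Gbp2b to 199 ± 95.6 CPM (at least 5260-fold), Iigp1 from 0.72 ± 0.326 to 1950 ± 179 CPM and Serpina3g from 0.539 ± 0.314 to 1220 ± 204 CPM. Gbp10 was 11800-fold higher (2120 to 468000) and Sectm1a 2030-fold (693 to 9830). Nos2 rose from 0.0651 ± 0.0307 to 43.7 ± 47.4 CPM (log2 9.34, SE 1.18, adjusted p = 1.04e-05). Cp, which encodes ceruloplasmin, a transcript studied as a GAIT target, was called in the knockout at 7.92 ± 8.63 against 1.14 ± 0.651 CPM (log2 2.84, SE 0.768, adjusted p = 0.0146). Knockout IFN 5 carried much of this, with Cp at 17.9 CPM against 2.8 and 3.09 CPM in knockout IFN 4 and 6, and without it the log2 fold change was 1.40 (adjusted p = 0.215). In wild type the change of Cp was 1.60 (SE 0.758, adjusted p = 0.165), and the test of the difference gave adjusted p = 1. Mrc1 fell from 305 ± 162 to 17.2 ± 8.41 CPM (log2 -4.15, adjusted p = 2.31e-06). Mmp12, the macrophage elastase, fell from 437 ± 110 to 19.8 ± 3.25 CPM (log2 -4.47), Nptx1 from 460 ± 123 to 25.2 ± 14.5 CPM (log2 -4.19). Cxcl2, a chemokine for neutrophils, fell from 19.7 ± 11.9 to 1.05 ± 0.647 CPM (log2 -4.17, adjusted p = 0.00509). Mamdc2, F13a1, Gsta3, Slc6a4 and Hpgd were the other large falls. Vegfa, Ccl22, Arg1, Chil3, Retnla, Csf1r, Adgre1, Lyz2 and Rpl13a were not called.

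In the knockout edgeR called 2697 genes, 1579 higher and 1118 lower after IFN, of which 835 and 580 changed at least 2-fold. On log2(TPM + 1) limma called 4025, of which 21.5% were higher against 58.5% here, and the median of all genes was -0.307. Camera called 13 lists, and 3 held with an estimated correlation: interferon-gamma response (38 of 38 higher, median 6.30, 9.14e-54; 0.00162 with an estimated correlation), MHC class I (23 of 23, median 2.85, 1.33e-26; 0.0267) and inflammatory M1 genes (13 higher and 1 lower, or 14 and 1 over the list alone, median 1.65, 5.19e-07; 0.0267). Type I interferon response genes were higher in 41 of 44, or 42 adjusted over the list alone (median 3.48, 1.09e-27), integrated stress genes in 10 with 1 lower, or 12 and 1 (0.68, 0.000171), and complement genes in 11 with 1 lower, or 12 and 1 (1.73, 7.14e-06). Each of these lists had adjusted p = 0.128 with an estimated correlation. MHC class II genes were higher in 11 of 12 (median 3.78, 3.11e-12; 0.072 with an estimated correlation) and glycolysis genes in 6 of 20, or 7 (0.39, 0.000119; 0.154 with an estimated correlation). Zbp1 rose from 2.62 ± 1.06 to 396 ± 107 CPM, Cd74 from 614 ± 314 to 8380 ± 1280 CPM, Wars from 52.1 ± 12 to 402 ± 21.5 CPM and C1ra from 4.15 ± 0.528 to 91.3 ± 34 CPM. Oxidative phosphorylation genes were higher in 36 of 75, or 43 over the list alone (median 0.71, 3.11e-12; adjusted p = 0.643 with an estimated correlation), as was Cox8a (144 ± 14 to 320 ± 27.7 CPM). Ribosomal proteins were higher in 21 of 80, or 22, with 74 above 0 (median 0.39, 4.01e-06; adjusted p = 0.776 with an estimated correlation), and Rps27 rose from 108 ± 16.3 to 324 ± 79.4 CPM (log2 1.58, adjusted p = 0.00056). The p53 targets (6 higher, 1 lower, median 0.48, 0.0289) and lysosome genes (10 and 2, or 11 and 3, median 0.15, 0.0383) had the same adjusted p = 0.776 with an estimated correlation, with Cdkn1a rising from 402 ± 71.9 to 918 ± 212 CPM. Glutathione and NRF2 targets fell in 15 of 25, or 17 (median -0.73, 3.18e-06; 0.211 with an estimated correlation), with Cat at 148 ± 18.2 against 541 ± 139 CPM. Fibroblast markers had 0 calls, a median of 0.0253, a mean of -0.149 and camera's adjusted p = 0.51.

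IL4 changed fewer genes than IFN, and wild type cells are described first. Arg1 rose from 0.496 ± 0.431 to 1000 ± 531 CPM (log2 11.05, SE 0.832, adjusted p = 6.16e-07), Chil3, a chitinase-like lectin, from 0.0428 ± 0.0741 to 151 ± 95.2 CPM (log2 11.45, adjusted p = 3.99e-06), Mrc1 from 296 ± 12.3 to 1770 ± 155 CPM (log2 2.58, adjusted p = 0.000306), and Mgl2, a lectin, from 0.113 ± 0.0979 to 118 ± 58.3 CPM. Retnla rose from 0 counts to 828 ± 901 CPM, at least 23000-fold higher (adjusted p = 0.00226). Rnase2a (at least 1900-fold), Pdcd1lg2, which encodes PD-L2 (at least 600-fold), Tuba8 (at least 158-fold) and Scn3a (789-fold, 218 to 6520) were the other large rises. The chemokine Ccl22 rose from 3.15 ± 1.86 to 23.8 ± 13.1 CPM (log2 2.93, adjusted p = 0.00424). Cx3cr1 fell from 171 ± 30.6 to 4.89 ± 1.94 CPM (log2 -5.12, adjusted p = 1.72e-05). Fcrl1 fell from 20.7 ± 3.2 to 1.93 ± 0.57 CPM (log2 -3.40) and Camsap3 from 29.5 ± 13.7 to 2.66 ± 1.2 CPM (log2 -3.46). Cav1, the caveolin, fell from 132 ± 82.1 to 14.3 ± 7.74 CPM (log2 -3.21, adjusted p = 0.039). Mycl, Ifit3b, Adgre4 and Dner were also among the 8 largest falls. Cp, Vegfa, Cxcl9, Cxcl10, Irf1, Nos2, Lyz2, Csf1r, Adgre1 and Rpl13a were not called.

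edgeR called 1063 genes in IL4-treated wild type cells, 621 higher and 442 lower, of which 350 and 272 changed at least 2-fold. The count fell to 704 without wild type untreated 2, 656 without wild type untreated 3, 645 without wild type IL4 8 and 239 without the libraries that held Y-linked transcripts, which left 1 wild type IL4 library. On log2(TPM + 1) limma's calls were 41.1% higher against 58.4%, with the median of all genes at -0.105. Of 37 IL4 M2 genes 27 were higher, or 30 adjusted over the list alone (median 3.21, 4.09e-36; adjusted p = 7.75e-06 with an estimated correlation), such as Cish (0.433 ± 0.183 to 38.1 ± 13 CPM) and Cdh1 (0.576 ± 0.309 to 37.7 ± 9.55 CPM). This list alone of the 10 called by camera held with an estimated correlation. MHC class II genes were higher in 6 of 12, or 7 with 1 lower (median 1.66, 0.000212), and dendritic cell markers in 3 of 9 (median 0.75, 0.0368), with Cd74 rising from 437 ± 32.2 to 2220 ± 937 CPM and Itgax from 55.7 ± 43.8 to 764 ± 190 CPM. Type I interferon response genes fell in 11 of 44, or 17 (median -1.27, 9.68e-12), and M1 genes in 6 of 23 with 1 higher (median -0.62, 0.0183), with Ifit3 at 2.66 ± 1.51 against 24.5 ± 11.2 CPM and Tnf at 9.8 ± 2.34 against 29.9 ± 1.53 CPM. These 4 lists had adjusted p = 0.587 with an estimated correlation. Ribosome biogenesis genes were higher in 4 of 41 (median 0.30, 4.92e-05) and glycolysis genes in 5 of 20, or 5 with 2 lower (0.14, 0.0368), both with adjusted p = 0.661 with an estimated correlation, as in Bop1 (49.9 ± 2.82 to 70.6 ± 7.88 CPM) and Pfkp (69.2 ± 2.57 to 203 ± 36.3 CPM). Oxidative phosphorylation genes were higher in 4 of 75, or 1 (0.34, 2.32e-07; Sdha 220 ± 7.58 to 320 ± 32.1 CPM), and p53 targets in 3 with 1 lower, or 6 and 1 (0.44, 0.0368; Cdkn1a 218 ± 40.6 to 465 ± 90.5 CPM). With fibroblast markers (median -1.50, 0 calls, 0.0183; Col1a1 95.1 ± 33 against 273 ± 76.6 CPM) these had adjusted p = 0.72 with an estimated correlation. Interferon-gamma response genes were not called as a list (4 higher and 9 lower of 38, 0.0617), yet Socs1 rose from 1.57 ± 0.543 to 52.8 ± 24 CPM and Fcgr1 fell from 107 ± 10 to 29.8 ± 7.88 CPM. Atp6v0d2 rose from 126 ± 35.2 to 711 ± 19.9 CPM and Cd14 fell from 295 ± 70.7 to 49.7 ± 19.7 CPM.

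Knockout cells responded to IL4 in the same markers. Arg1 rose from 0.277 ± 0.123 to 692 ± 453 CPM (log2 11.28, SE 0.871, adjusted p = 1.04e-06), Retnla from 0 counts to 1130 ± 754 CPM (at least 30000-fold, adjusted p = 0.00208), Mgl2 from 0.0885 ± 0.0853 to 161 ± 125 CPM (log2 10.77). Chil3 rose from 1.7 ± 1.51 to 224 ± 147 CPM (log2 7.14, adjusted p = 1.05e-05), Mrc1 from 305 ± 162 to 1740 ± 456 CPM (log2 2.51) and Ccl22 from 3.3 ± 1.12 to 26.1 ± 15.4 CPM (log2 2.98). Rnase2a (at least 2610-fold), Scn3a (at least 639-fold), Msx3 (at least 368-fold), Pdcd1lg2 (569-fold, 194 to 2760) and Cldn11 (650-fold, 116 to 25700) rose as well. Cx3cr1 fell from 158 ± 50 to 3.76 ± 2.82 CPM (log2 -5.36, adjusted p = 1.58e-05), Nptx1 from 460 ± 123 to 34.3 ± 16.8 CPM (log2 -3.74). Cav1 fell from 227 ± 169 to 15.6 ± 3.78 CPM (log2 -3.87, adjusted p = 0.015), the receptor Notch4 from 29.3 ± 5.99 to 2.71 ± 0.252 CPM (log2 -3.43) and Ifit3 from 13.5 ± 6.22 to 1.27 ± 0.446 CPM (log2 -3.39). Mycl, Dner and Fcrl1 fell too. Cp, Vegfa, Cxcl9, Cxcl10, Irf1, Nos2, Lyz2, Csf1r, Adgre1 and Rpl13a were not called either.

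edgeR called 1186 genes in IL4-treated knockout cells, 670 higher and 516 lower, of which 333 and 284 changed at least 2-fold. A fit on the 6 libraries alone called 422, and 734 remained as a count without knockout untreated 2. On log2(TPM + 1) 27% of limma's calls were higher against 56.5%, with the median of all genes at -0.164. IL4 M2 genes were higher in 29 of 37, or 30 adjusted over the list alone (median 3.90, 5.89e-35; adjusted p = 9.27e-06 with an estimated correlation), such as Cish (0.831 ± 0.228 to 48.2 ± 2.9 CPM) and Cdh1 (0.34 ± 0.307 to 42.2 ± 24.3 CPM). The other 8 lists called by camera lost their calls with an estimated correlation. Ribosomal proteins were higher in 8 of 80, or 16, with 79 above 0 (median 0.43, 3e-13; Rps26 367 ± 69.7 to 602 ± 70.5 CPM), oxidative phosphorylation genes in 14 of 75, or 30 (0.56, 1.03e-13; Atp5c1 126 ± 16.5 to 205 ± 21.6 CPM) and MHC class II genes in 6 of 12, or 7 (1.49, 0.000201; H2-DMa 26.7 ± 5.16 to 132 ± 24.7 CPM), each with adjusted p = 0.72 with an estimated correlation. The p53 targets were higher in 5 of 25 with 2 lower, or 9 and 2 (0.41, 0.00704; Ccng1 177 ± 16 to 321 ± 75.9 CPM), and type I interferon response genes fell in 4 of 44, or 12 with 1 higher (-0.88, 4.51e-06; Rtp4 28.5 ± 8.13 to 5.78 ± 3.58 CPM), both with adjusted p = 0.723 with an estimated correlation. Ribosome biogenesis genes (1 higher, 0 over the list alone, median 0.23, 0.00789; 0.824 with an estimated correlation) included Nop14, cholesterol synthesis genes (1 of 24, median 0.42, 0.0364; 0.858 with an estimated correlation) Dhcr7 (27.6 ± 3.18 to 57.3 ± 8.64 CPM), and osteoclast markers (3 of 8, or 4, median 0.65, 0.0289; 0.499 with an estimated correlation) Itgb3 (12.3 ± 8.25 to 71.9 ± 23.7 CPM). Fibroblast markers had a median of 0.94 (0.404).

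**Figure D3:**
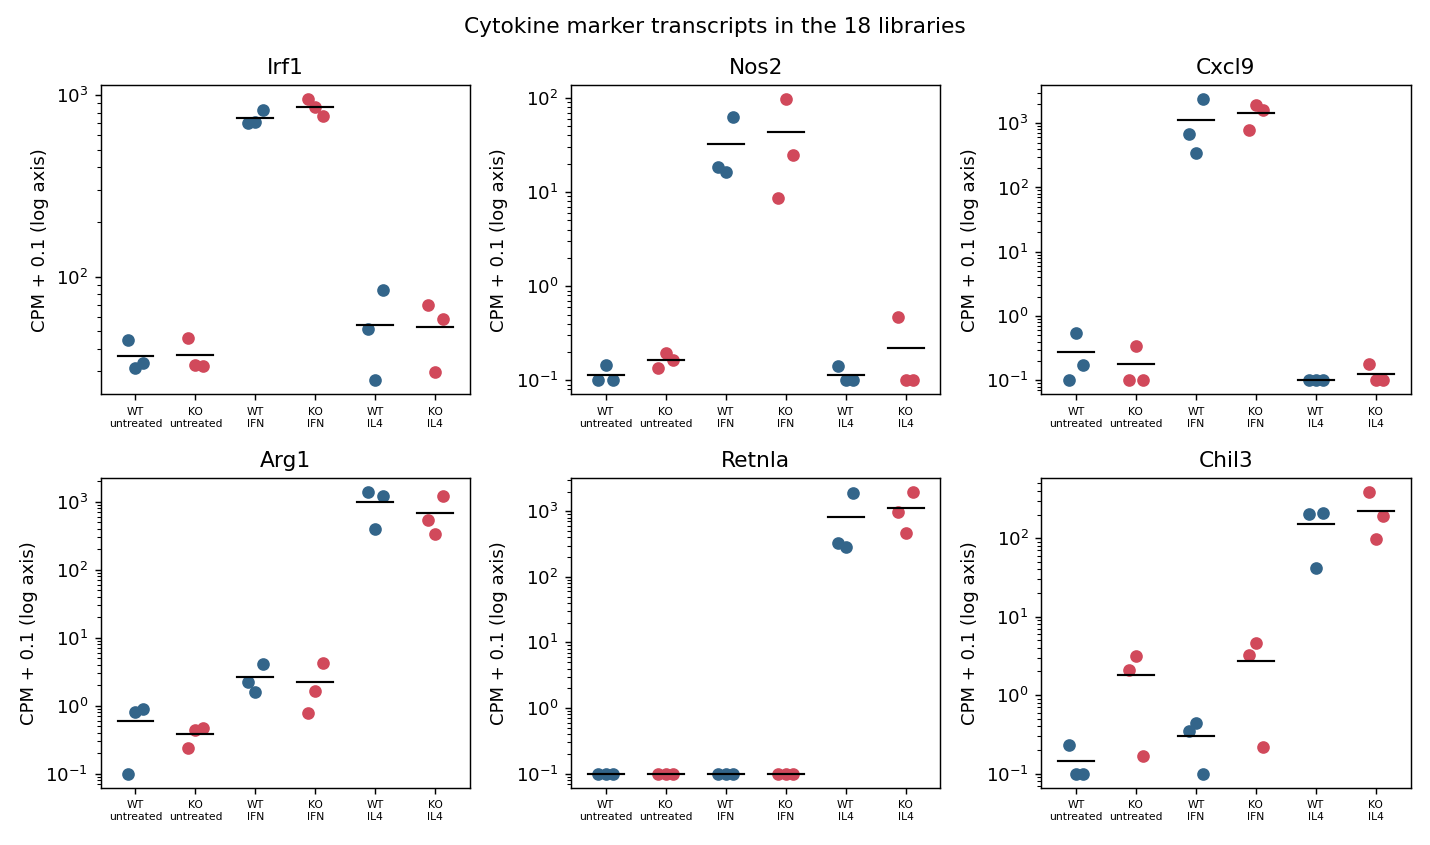
Irf1, Nos2, Cxcl9, Arg1, Retnla and Chil3 as CPM + 0.1 on log axes, one point per library with the mean of each group as a line. IFN raised Irf1 to 750 CPM in wild type and 856 CPM in the knockout, and IL4 raised Arg1 to 1000 and 692 CPM.

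The responses of both genotypes were set side by side gene by gene. After IFN 1110 genes were called higher and 620 lower in both, where independent lists would share 175 and 84.4, and 3 were called in opposite directions. Log2 fold changes correlated at Pearson's r = 0.777 (Spearman's rho 0.671) across all tested genes, which are not independent replicates. Over the 1733 genes called in both, the median ratio of the knockout to the wild type log2 fold change was 1.04. After IL4, 478 genes were higher and 293 lower in both, against 33.2 and 18.2 for independent lists, with 0 opposite calls, r = 0.702 (rho 0.605) and a median ratio of 0.981 over 771 genes.

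**Figure D4:**
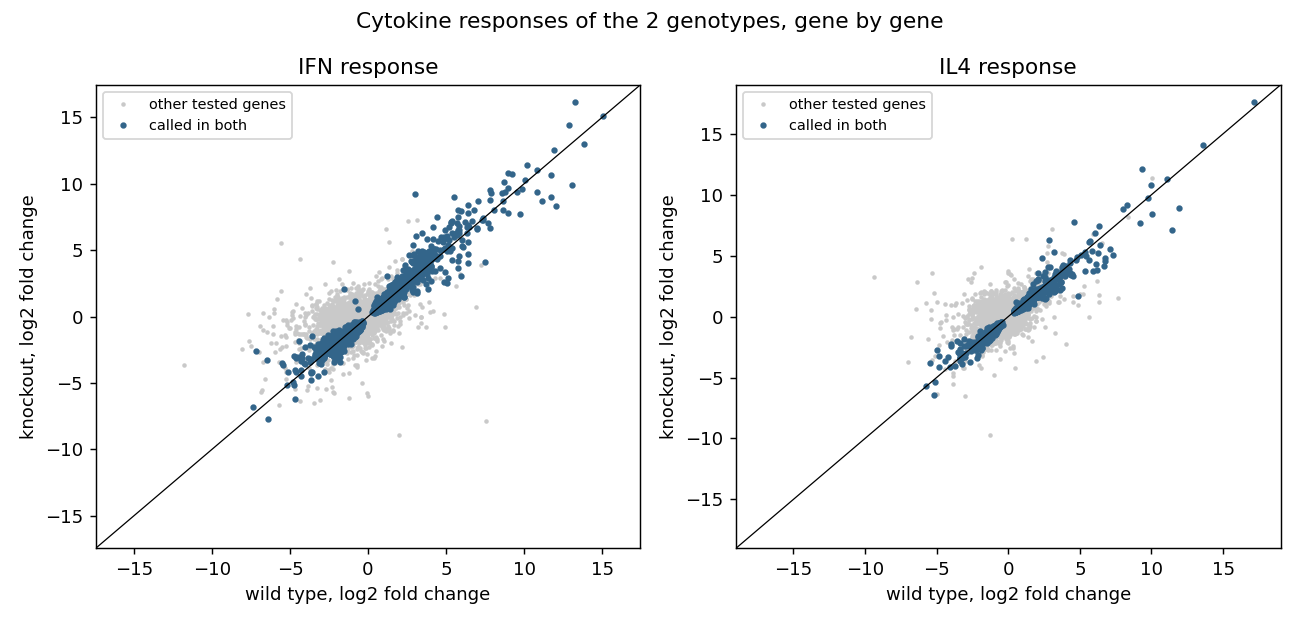
Log2 fold change of each tested gene in wild type (horizontal) and knockout cells (vertical) for IFN and IL4, with genes called in both genotypes in blue and the line of equal change. Among the blue points 1730 of 1733 lie on the same side of 0 in both genotypes for IFN and 771 of 771 for IL4.

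Whether the knockout altered the responses was tested as the difference of the responses. edgeR called 0 genes for IFN, with a lowest adjusted p of 0.116, 617 genes at an unadjusted p under 0.05, 26 calls by DESeq2 and 0 by limma. With the position of the title number within each group as a block, chosen after seeing the data, 29 genes were called, 27 higher and 2 lower. That block joined wild type untreated 2 with wild type IFN 5 and IL4 8, which unlike it held Y-linked transcripts. Without a block, leaving out wild type IFN 6 gave 9. The lowest p fell to ribosomal protein transcripts: Rps27 (log2 difference 2.32, SE 0.381, adjusted p = 0.116), Rpl39 (1.77, SE 0.346, adjusted p = 0.391) and Rps21 (1.97, SE 0.39, adjusted p = 0.391), with the predicted gene Gm2000 beside them. Rps27 was at 299 ± 73.8 CPM in untreated wild type, 180 CPM in IFN-treated wild type, 108 ± 16.3 CPM in untreated knockout and 324 ± 79.4 CPM in IFN-treated knockout libraries. For IL4 edgeR called 0 genes, with 249 at an unadjusted p under 0.05, 1 call by DESeq2 and 0 by limma, and the lowest adjusted p was 1. Ogn, Pdcd10, Pth1r and P2rx5 had the lowest p there, with log2 differences of 2.73, 0.63, 4.78 and -3.18. Of the preset genes Irf1 differed by 0.18 (SE 0.469) for IFN and -0.05 (SE 0.476) for IL4, Cxcl10 by 0.53 (SE 1.01) for IFN, Cxcl9 by 1.54 (SE 2.83), Arg1 by 0.23 (SE 1.54) for IL4 and Chil3 by -4.31 (SE 2.12) for IL4, with adjusted p = 1 in each. Mrc1 differed by -1.30 for IFN (SE 0.515, adjusted p = 0.898).

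Camera called 9 lists in the difference of the IFN response and 5 in that of the IL4 response, and 0 with an estimated correlation. Ribosomal proteins differed by a median of 0.73 for IFN, with 78 of 80 above 0 and 40 when adjusted over the list alone (2.54e-42; adjusted p = 0.789 with an estimated correlation). For IL4 their median difference was 0.38, with 77 of 80 above 0 (4.99e-19; adjusted p = 0.992 with an estimated correlation). Type I interferon response genes differed by 0.78 for IFN (1.75e-06; 0.799 with an estimated correlation) and 0.34 for IL4 (0.00238; 0.992). In the same order, Zbp1 differed by 1.84 (SE 0.585, adjusted p = 0.775) and 1.41 (SE 0.647, adjusted p = 1). Fibroblast markers differed by 2.37 for IFN (7.44e-06; 0.789 with an estimated correlation) and 2.20 for IL4 (2.92e-07; 0.992), all 14 above 0 in both. Their summed level was 850.5, 990.9 and 1024 CPM in untreated wild type libraries, and 1215 CPM in knockout IL4 9 and 814.6 CPM in knockout IFN 6.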

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

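The 14 list differences below were selected by a fixed rule. The test of length and the splits of the planned comparisons were planned before the results were seen. All other tests of explanations in this part were chosen only after results were seen.

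By camera with its preset correlation, 9 lists differed in the IFN response of the knockout from that of wild type: ribosomal proteins by a median of 0.726, ribosome biogenesis -0.211, interferon-gamma response 0.472, type I interferon response 0.783, MHC class I 0.401, oxidative phosphorylation 0.418, cell cycle -0.508, macrophage identity 0.254 and fibroblast markers 2.37. For the IL4 response 5 differed: ribosomal proteins 0.384, type I interferon response 0.342, glycolysis -0.19, oxidative phosphorylation 0.188 and fibroblast markers 2.2. None held with an estimated correlation, where the adjusted p ran from 0.789 to 0.863 for IFN and was 0.992 for IL4. Of 265 genes named over these contrasts, 25 moved in opposite directions in some pair of contrasts, and the test of the difference by edgeR without a block called 0 of them, with a lowest adjusted p of 0.116. DESeq2 and the position block, chosen later, called some of them in the difference of the IFN response, such as Rps27, Rps21, Rpl39 and Rpl26 by both.

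The first pattern weighed was that the same genes were called between genotypes in several treatments, with 49 called by the mean knockout effect. A large loss of macrophages from the knockout cultures was not borne out, as the macrophage identity list without Lyz2 had a median of 0.0678 (bootstrap SE 0.0422, 23 genes). A smaller shift in cell content would hardly move this median and is open. Summed fibroblast markers were at 955.1, 147.2 and 371.3 CPM in untreated, IFN-treated and IL4-treated wild type, and at 282, 364.4 and 539 CPM in the knockout. Donor sex was not borne out for the genes shared between treatments, as far as the Y-linked covariate could show. All 10 genes called in untreated cells passed with it. Only wild type untreated 1 held these transcripts there, so that fit leaned on wild type untreated 2 and 3, which were unusually alike. Fewer passed elsewhere (3 of 8 after IFN, 2 of 8 after IL4, 25 of the 49), but the log2 fold changes of the shared genes moved little. After IFN they were -2.27, -2.51, 2.16 and 0.955 with the covariate for Cnbd2, Rab4a, Pira2 and Fam177a, against -2.04, -2.51, 2.34 and 0.985 without. With the Y-linked libraries left out, Cnbd2, Pira2 and Fam177a stood at -2.58, 1.84 and 0.986 in untreated cells, against -2.45, 2 and 1.04. Pira2, Fam177a and Rpl26 were then no longer called there. Chromosome segments of another strain are open: 14 pairs of the 49 genes lay within 1 Mb, none of them near Rpl13a, where in 10000 random draws of a permutation test the median was 2 and the most 12 (permutation p = 1e-04, the smallest possible), but the control sets gave 27 pairs for the IFN and 5 for the IL4 response of wild type. The list of genes beside Rpl13a had a median of -0.0139 in the mean knockout effect (camera adjusted p = 0.343).

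Lower ribosomal protein transcripts in untreated knockout cells were weighed next. A general loss of short transcripts was tested on 646 other genes matched in annotated length. Their median was -0.0799 (bootstrap SE 0.0141) against -0.741 for ribosomal proteins (bootstrap SE 0.0258), which ran from -0.925 to -0.617 with single libraries left out. Annotated length was the median over a gene's protein-coding transcripts, which put Col3a1 at 737 nt, and abundance was not matched. The matched set can therefore hold long transcripts, so a loss limited to short ones is open. Scaling was not the source, as the median on the deposited TPM was -0.591. For an effect of the genotype in all treatments, the highest of the 3 medians was -0.00428 (bootstrap SE 0.028) after IFN, so no lowering was seen there. This SE holds the libraries fixed, and the ribosomal protein share of counts ran from 2.308% to 3.63% between knockout IFN libraries. A smaller effect after IFN is therefore open. Ribosomal proteins made up 4.634%, 3.232% and 4.543% of counts in untreated, IFN-treated and IL4-treated wild type and 3.006%, 3.175% and 3.841% in the knockout, and mitochondrial transcripts 5.056%, 3.442% and 5.935% against 3.808%, 3.446% and 4.848%.

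Higher p53 targets in the knockout formed the third pattern, with a median of 0.421 in the mean knockout effect. Donor sex did not account for it, as the median with the Y-linked covariate was 0.481. Whether the list moved as a whole is open, because its adjusted p with an estimated correlation was 0.427. Within treatments the median fell from 0.324 to 0.112 without knockout untreated 1. It fell from 0.393 to 0.213 without knockout IFN 4 and from 0.354 to 0.181 without knockout IL4 7. These libraries share a position and deviated alike in part (r = 0.434 to 0.609), so much of the pattern may rest on a shared source.

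Libraries were also regrouped, and each split was tested as the real one was. For comparisons of 2 groups each possible split of the same size was used. For the differences of responses and the mean knockout effect, 100 splits were used: the real one and others drawn at random. For knockout against wild type 2 of 10 splits gave as many calls in untreated cells (10 real, 59 highest other), 2 of 10 after IFN (8 real, 39 highest other) and 1 of 10 after IL4 (8 real, 1 highest other). The split with 59 exchanged wild type untreated 1 and knockout untreated 3, so the libraries hold structure other than genotype that gives more calls than genotype does. Among the 3 other splits that parted as many pairs of the same number as the real one, the highest count was 0 in each of the 3 treatments, and among 6 such splits of the mean knockout effect it was also 0. For the cytokine responses 1 of 10 splits gave as many, the real one: 2332 against 0 for IFN in wild type, 2697 against 0 in the knockout, 1063 against 2 for IL4 in wild type and 1186 against 0 in the knockout. With 10 splits these designs are too small for a share under 0.05. The differences of responses had 26 of 100 splits as large for IFN (617 genes at an unadjusted p under 0.05, 2775 highest other) and 76 of 100 for IL4 (249 and 4614), so their counts were no larger than other groupings gave. For the mean knockout effect 2 of 100 were as large (49 real, 62 highest other).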

How the results depend on the processing

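Alternatives that used the Y-linked transcripts, the summed libraries, the mean knockout effect or the position block were chosen after seeing the data, and the others were planned. No named gene that was called in the main fit or in the alternative reversed its direction under any setting run. Genes called in neither fit were not compared for direction. Lyz2 kept its call between genotypes in each setting, while the other calls between genotypes were lost when only the groups compared were fitted. The cause was not tested for any moved result below, except that fits with fewer libraries have less power. DESeq2 called 83 genes between genotypes in untreated cells, 42 after IFN and 30 after IL4, 26 and 1 in the differences of the IFN and IL4 responses, and 201 in the mean knockout effect. It gave Rpl13a -1.46 in untreated cells (adjusted p = 0.0303). The strict filter left 6 in untreated cells and 32 in the mean knockout effect. Only the groups compared gave 1, 1 and 1 between genotypes, and 422 for IL4 in the knockout. Untreated wild type libraries 2 and 3 summed gave 5. With the Y-linked covariate the counts between genotypes were 39, 5 and 3, with 10, 3 and 2 of the original calls kept, the interferon-gamma list median after IFN was -0.0767 and that of oxidative phosphorylation -0.116. Leaving out the libraries with Y-linked transcripts left 1 wild type library after IFN and 1 after IL4, and the counts were 1 after IFN, 1 after IL4, 975 for the IFN and 239 for the IL4 response of wild type, and 18 for the mean knockout effect. On that 1 wild type IFN library the list medians were 0.014 (interferon-gamma), -0.133 (MHC class I) and -0.239 (oxidative phosphorylation) between genotypes after IFN, and -0.069 for MHC class I in the difference of the IFN response, which was 0.371 with the covariate. Camera called lists 83 times, and with an estimated correlation 8 of these calls held. Fry called 36 in all, of which 29 were among the 83. At an adjusted p under 0.01 the overlaps fell from 6 to 1 between knockout effects, from 1730 to 1057 for IFN and from 771 to 399 for IL4. Leaving out single libraries gave 1 (wild type untreated 2) to 11 (wild type untreated 1) between untreated genotypes, 2 (wild type IFN 5) to 6 (knockout IFN 6) after IFN, and 1 (knockout IL4 7) to 4 (wild type IL4 7) after IL4. It gave 645 (wild type IL4 8) to 950 (wild type untreated 1) for IL4 in wild type, 734 (knockout untreated 2) to 1153 (knockout IL4 7) for IL4 in the knockout, and 0 (wild type untreated 1) to 9 (wild type IFN 6) for the difference of the IFN response. The oxidative phosphorylation median between genotypes ran from -0.0584 (wild type IFN 4) to 0.347 (wild type IFN 6) after IFN and from -0.264 (wild type IL4 7) to 0.0718 (knockout IL4 7) after IL4, and that of type I interferon genes after IL4 from -0.577 (knockout IL4 7) to 0.111 (wild type IL4 9). That of cell cycle genes ran from -1.01 (knockout untreated 3) to -0.0874 (knockout untreated 1) in untreated cells and from -0.81 (knockout IL4 9) to 0.0253 (knockout IL4 7) after IL4. On log2(TPM + 1) the share of higher calls was 54.5% of 11 against 20% in untreated cells and 25% of 8 against 37.5% after IFN.

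With the title number as a block the counts between genotypes were 96 in untreated cells, 24 after IFN and 27 after IL4, and 246 for the mean knockout effect, and Rpl13a in untreated cells was -1.59 (adjusted p = 0.0382). Only IL4 met the rule for pairing: over the genes above a mean log2 CPM of 2 the same numbers correlated at 0.746, 0.0725 and 0.573 in untreated and 0.371, 0.0356 and 0.265 in IFN-treated cells. Over all genes IFN would have met it (0.296, 0.135 and 0.276) and untreated cells not (0.597, 0.0417 and 0.358). The counts with a block had been seen by then, so the stricter reading was kept. With the position of the number within each group as a block, the responses to IFN had 4182 calls in wild type and 4446 in the knockout, those to IL4 2407 and 2736, and the difference of the IFN response 29. These counts are uncertain, because the block joined wild type untreated 2 with wild type IFN 5 and IL4 8, which unlike it held Y-linked transcripts. Of the named genes tested, the title-number block gained a call for 12 and left 258 as they were, and the position block gained 28, lost 1 and left 473. The list calls stayed, except that 2 were lost with the position block.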

Other observations

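What follows was chosen only after results were seen, including the mean knockout effect and the position block.

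Averaged over the 3 treatments, edgeR called 49 genes between genotypes, 29 higher and 20 lower in the knockout. The standard errors treat the 9 libraries of a genotype as independent, although libraries at the same position deviated alike in part, so they can be too small. The p53 targets Phlda3 (log2 1.42, SE 0.192, adjusted p = 0.00149), Cdkn1a, the inhibitor of the cell cycle (0.82, SE 0.13, adjusted p = 0.00597), Zmat3 (0.91, adjusted p = 0.046) and Aen (0.42, adjusted p = 0.0383) were higher. Rpl13a was lower (-1.11, SE 0.225, adjusted p = 0.046), as were Lyz2, Cnbd2 (-2.25, SE 0.189, adjusted p = 1.47e-05), Rab4a (-1.84, SE 0.156, adjusted p = 1.47e-05) and Mid1 (-4.61, SE 0.837, adjusted p = 0.0204). Of the lists that camera called, the 3 with the lowest adjusted p were the p53 targets (median 0.42, adjusted p = 2.52e-11), cell cycle genes (-0.58, 7.63e-24; knockout untreated 1 and IL4 7 carried most of the change within their treatments) and ribosomal proteins (-0.33, 7.21e-35), and for each adjusted p = 0.427 with an estimated correlation. The p53 medians within treatments fell furthest without knockout untreated 1, IFN 4 or IL4 7. Camera also called type I interferon response (-0.282, 0.000687) and oxidative phosphorylation genes (-0.0975, 0.00629). Higher were glutathione and NRF2 targets (0.177, 0.00753), lysosome (0.0932, 0.00753), inflammatory M1 (0.226, 0.00965), dendritic cell (0.938, 0.0181) and glycolysis genes (0.0997, 0.0478). None of these lists held with an estimated correlation. Among neighbouring calls were Fam177a, Srp54a and Srp54b on chromosome 12, Lyz1 and Lyz2, and Xlr genes of the X chromosome, and reads shared with near copies were not tested.

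With the position of the number within each group as a block, 29 genes were called in the difference of the IFN response, 27 higher and 2 lower, and 13 of them were also called by DESeq2 without a block. They included 9 ribosomal protein transcripts, such as Rps27 (log2 difference 2.35, SE 0.318, adjusted p = 0.0308), Rps21 (1.99, SE 0.326) and Fau (1.60, SE 0.281, adjusted p = 0.036), and Fkbp5 (-1.14) and Chaf1a (-1.28) were lower. The ribosomal protein list differed by a median of 0.755 (camera adjusted p = 9.47e-37; adjusted p = 0.674 with an estimated correlation). The block treated wild type untreated 2 as a match of wild type IFN 5 and IL4 8. Untreated 2 held 0 CPM of Y-linked transcripts, against 116.3 and 124.8 CPM in those libraries, so they did not all share a single donor. The block was thus not right for untreated 2, and the calls that rest on it are uncertain.

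Libraries at the same position within their groups deviated alike in part from the group means. Across genes, which are not independent replicates, wild type 1, 4 and 7 correlated at 0.422 to 0.516, wild type 3, 6 and 9 at 0.245 to 0.444, knockout 1, 4 and 7 at 0.434 to 0.609, knockout 2, 5 and 8 at 0.261 to 0.486 and knockout 3, 6 and 9 at 0.597 to 0.672. Wild type 2, 5 and 8 stood at 0.0789 to 0.336. Wild type untreated 2 correlated at 0.235 with wild type IFN 6 and 0.276 with wild type IL4 9, against 0.0789 with wild type IFN 5 and 0.134 with wild type IL4 8, and it lacked the Y-linked transcripts that those last 2 libraries held.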
